A study of Mus musculus with 6 samples.

How the data were processed

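Gene expression was measured on 6 Affymetrix mouse 430 2.0 arrays, which carry short oligonucleotide probe sets near the 3' ends of transcripts. Each array held RNA of naive CD8+ T cells from the spleen of wild-type or Nrdp1-/- mice. There was 1 array for each of the 2 genotypes at each of 3 conditions: untreated, and 4 h or 8 h with plate-bound anti-CD3 at 5 µg/ml and soluble anti-CD28 at 1 µg/ml. Groups were taken from the sample titles. The labels do not say how many mice gave each RNA. They do not say whether the arrays of a genotype share an animal, so the p-values measure the spread between these arrays, not between animals. With 1 array per genotype and time, that spread is how much the genotype difference varies over the 3 times. It may be technical or a real difference in response, and the 2 cannot be separated here. The RNA extraction text in the labels names whole colon, which conflicts with the sample titles. Markers of colon epithelium and smooth muscle were therefore examined on every array.

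The deposited values are MAS5 signal intensities on a linear scale, with MAS5 named in the submitters' processing notes without a version. The values themselves showed that the authors had scaled each array, since the mean without the lowest and highest 2% was 500.0 on all 6 arrays. Detection calls were not used here. MAS5 scales the whole array by 1 factor, so a change that moves most transcripts one way would be hidden by it. The median signal was between 61.5 and 68.6 per array. Ratios of 3' to 5' control probe sets, a sign of RNA integrity, were 0.815 to 0.894 for Gapdh and 1.39 to 1.53 for beta-actin. Their ranges in the 2 genotypes overlapped. The number of arrays limits the precision, and for dim genes so does signal over background.

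The table held 45101 probe sets, of which 64 were array controls and were left out. In the platform annotation 34945 probe sets had 1 gene symbol, 932 had several, and 9160 were not listed and are unnamed here. Symbols were looked up by Entrez identifier in NCBI RefSeq annotation of GRCm38.p6, where 34741 probe sets matched and 0 symbols changed. Among the 18193 genes with a probe set of 1 symbol, each gene was represented by its brightest probe set. Values were taken as log2(signal + 4.45), where 4.45 is the 10th percentile of all values, and fold changes of dim genes are understated on this scale. Genes whose probe set reached the median of its array on at least 2 of the 6 arrays were kept, which left 10829 genes. A condition in which a gene lay below the array median on every array was called dim. Its fold change is given as a lower bound against that median, as "at least N-fold".

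Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, Benjamini-Hochberg adjustment, threshold 0.05). The model held time and genotype as additive terms over all 6 arrays, with 2 residual degrees of freedom and 8.96 prior degrees of freedom. Each time was thus represented by 1 array of either genotype, and each genotype by its arrays at the 3 times. Whether the genotype difference was other in stimulated than in untreated cells was tested by adding a genotype-by-stimulation term, with 1 residual degree of freedom. There the prior degrees of freedom were estimated as infinite, so that test rested on the trend alone. Differences between 2 single arrays, such as Nrdp1-/- minus wild type at one time, have no replicate check and carry no p-value. For these, the median of a gene list was placed among 10000 random lists of the same size matched on deciles of mean expression, as a description of these arrays.

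The 29 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Named were a fixed set of genes (Rnf41, Zap70, Ubash3a, Ubash3b and genes of T cell activation), up to 8 risen and 8 fallen genes with the largest change among those past the threshold and moving the same way in both genotypes or at all 3 times, and up to 4 members of each list with the largest change. Genotype differences without a test added up to 8 genes per direction that differed at least 2-fold at all 3 times, up to 6 per direction at each time, and up to 8 whose induction differed at least 2-fold at both times, with a brightness minimum at the 75th percentile for the last 2 kinds. Other list members and genes outside this rule were named after their values were seen where a count of called members is spelled out. Alternatives were quantile normalization, centring each array on its median, pseudocounts of 1 and of the 30th percentile (24.3), no filter on dim probe sets, a filter at the 70th percentile, the mean of a gene's probe sets, eBayes without the trend, a 2-fold minimum, the stimulated arrays alone, and leaving out each array in turn. An interaction test with the spread of the additive model, and median centring for the list medians of the difference in change, were added after the data were seen.

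The tests were checked on simulated arrays of the 10829 genes with the observed means and spread, in which 200 genes were changed. For the comparison of 4 h with untreated cells, 44.8% of genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 93.9% of those changed by 2 were recovered, with 8 false calls (5.23% of the calls). For the genotype comparison the shares were 59.7%, 83.6% and 95.5%, with 22 false calls (12.2%). For the genotype-by-stimulation term they were 10.4%, 55.2% and 74.2%, with 24 false calls (20.5%). In this simulation, a single set for each comparison, the genotype and genotype-by-stimulation tests thus made more false calls than the 5% aimed at. Figures were drawn with matplotlib.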

Results

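Expression was measured in naive CD8+ T cells from the spleens of wild-type mice and of mice lacking Nrdp1. Nrdp1 is an E3 ubiquitin ligase encoded by Rnf41. The cells were untreated or were stimulated through the T cell receptor and CD28 for 4 h or 8 h, with 1 array per genotype and condition and 6 arrays in all. The comparisons addressed which transcripts respond to stimulation and which differ without Nrdp1. This ligase has been studied for its action on Zap70, a kinase of T cell receptor signalling, together with the phosphatases Ubash3a and Ubash3b. The genotypes had no replicate arrays at any one time. The number of arrays limits the precision, and values are log2 differences of MAS5 signal with their standard error from limma (SE, 6 arrays) unless given otherwise.

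The targeted gene was examined first. The brightest of 4 probe sets for Rnf41 differed between Nrdp1-/- and wild-type arrays by -0.46 in untreated cells, -0.21 at 4 h and -0.42 at 8 h. Its mean difference of -0.36 ± 0.12 did not pass the threshold (limma, adjusted p = 0.128). A dimmer probe set was lower at every time, at -1.66, -1.18 and -0.91, with a mean of -1.25. The remaining pair had mean differences of 0.00 and 0.25. Which of these probe sets lies in the deleted part is not known here, so a probe set outside it checks nothing about the labels. Among the known partners, Zap70 did not pass the threshold between genotypes (-0.05 ± 0.10, adjusted p = 0.862), nor did Ubash3a (-0.18 ± 0.13, adjusted p = 0.547) or Ubash3b (-0.45 ± 0.13, adjusted p = 0.0787). None of the 9 measured genes of the Nrdp1 and partner list was called between genotypes in limma, with 3 at an unadjusted p under 0.05, 0 without the intensity trend, and 2 lower when adjusted over the list alone.

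After 4 h of stimulation the CD8+ T cells showed a strong induction of cytokine and chemokine transcripts. Il2, the T cell growth factor, rose by 6.77 ± 0.15 on the log2 scale, and since it was dim in untreated cells this was at least 42.4-fold. The chemokine Ccl3 rose by 6.02 ± 0.24 and Ccl4 by 4.83 ± 0.12. Ifng, the interferon of T and natural killer cells, rose by 5.25 ± 0.27 and Tnf by 4.21 ± 0.20. Csf2 (at least 7.80-fold), the TNF family ligand Tnfsf14 (at least 14.8-fold), Cxcl9 (at least 4.73-fold) and Cxcl10 (at least 22.5-fold) rose from dim levels. Of 19 measured cytokine and chemokine genes 12 rose, 0 fell and 13 rose when adjusted over the list alone. Regulators of the immediate early response rose with them, in 15 of 24 genes, with 20 adjusted over the list alone. The largest changes there were in Nr4a3 (4.37 ± 0.15), Nr4a1 (4.03 ± 0.15), Nr4a2 (3.79 ± 0.22) and Egr2 (2.92 ± 0.15). Egr1 rose by 2.25 ± 0.10 and Myc by 2.14 ± 0.11, while Ier3 fell (-0.65).

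Surface molecules of activated T cells changed at 4 h as well. Il2ra, the high-affinity subunit of the IL-2 receptor, rose by 3.78 ± 0.17 (at least 9.60-fold), Cd83 by 3.25 ± 0.16, the costimulatory receptor Tnfrsf9 by 2.91 ± 0.18 and the early activation marker Cd69 by 2.73 ± 0.18. In that list 9 of 13 genes rose, and 12 when adjusted over the list alone. Of 7 inhibitory receptors and ligands 5 rose (6 adjusted over the list alone), among them Cd274, which encodes PD-L1 (3.29 ± 0.21), Cd160 (2.21 ± 0.20) and Pdcd1 (1.30 ± 0.32). Among 12 regulators of effector differentiation 6 rose, led by Irf4 (3.31 ± 0.14), Irf8 (3.16 ± 0.25) and Bhlhe40 (2.19 ± 0.15), and adjusted over the list alone 6 rose and 1 fell. In the NF-kB list 15 of 18 genes rose, also when adjusted over the list alone, including Nfkbid (2.42 ± 0.15) and Bcl3 (1.97 ± 0.14). Of 22 negative regulators of signalling 10 rose and 3 fell (10 and 4 adjusted over the list alone). Spry1 (2.22 ± 0.20) and Cish (1.68 ± 0.20) were among the risen ones, and Dgka (-0.43), Ubash3a (-0.60) and Sla2 (-0.81) were the fallen ones. Gzmb, the cytotoxic protease granzyme B, rose by 1.74 ± 0.19, and Gzmk fell (-0.54 ± 0.12). They belonged to 4 risen and 1 fallen of 11 cytotoxic genes, or 5 and 2 adjusted over the list alone.

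Growth and metabolic genes changed as well. Of 28 ribosome biogenesis genes 26 rose at 4 h, also when adjusted over the list alone, with a median of 1.01. Polr1b, a subunit of RNA polymerase I, rose by 1.61 ± 0.19 and Nolc1 by 1.53 ± 0.13. Of 17 genes of amino acid transport, one-carbon metabolism and the ATF4 response 14 rose (14 adjusted over the list alone), led by the transporter Slc7a5 (2.75 ± 0.15), Shmt1 (2.50 ± 0.21) and Mthfd2 (2.43 ± 0.13). Hk2, the inducible hexokinase, rose by 2.14 ± 0.20 among 7 risen and 1 fallen (Slc2a3, -0.41) of 15 glycolysis genes, with the same counts adjusted over the list alone. Of 16 cholesterol synthesis genes 5 rose (6 adjusted over the list alone), led by Idi1 (1.17 ± 0.12). Of 10 chaperones 5 rose (6 adjusted over the list alone), led by Hspd1 (1.07 ± 0.10). Of 25 interferon response genes 14 rose (16 adjusted over the list alone), including Gbp2 (2.63 ± 0.21), Rtp4 (2.05 ± 0.13) and Irf1 (1.81 ± 0.10).

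Genes of naive and quiescent T cells moved down. Of 21 measured, 8 fell and 1 (Id3, 0.73 ± 0.13) rose at 4 h, and 11 fell and 1 rose adjusted over the list alone. Il6ra fell by 0.80 (-0.80 ± 0.11), and Tsc22d3 (-0.69 ± 0.12) and Tob1 (-0.63 ± 0.12) fell too. Klf2 (-0.15 ± 0.10), the IL-7 receptor gene Il7r (-0.09 ± 0.10), Rnf41 (-0.40 ± 0.14) and Ubash3b (-0.03 ± 0.16) did not pass the threshold. Of the 9 Nrdp1 and partner genes Zap70 rose and Ubash3a fell at 4 h (1 and 3 adjusted over the list alone). Of 27 components of T cell receptor signalling 1 rose and 4 fell (4 and 7 adjusted over the list alone). The risen gene was Zap70 (0.62 ± 0.12). Txk (-0.45 ± 0.11), Plcg1 (-0.44), Themis (-0.52 ± 0.11) and Nfatc2 (-0.65 ± 0.14) fell, and Nfatc2 took the opposite sign, 0.23, when all its probe sets were averaged. Of 18 G1 and S phase genes 3 rose, among them Cdk6 (1.03 ± 0.13) and Ccnd2 (0.97 ± 0.10), and Ccne1 fell (-0.55), with 4 and 2 adjusted over the list alone. Of 14 G2 and M phase genes 0 rose and Plk1 fell (-0.91 ± 0.22), also adjusted over the list alone, and 0 had a positive change at an unadjusted p under 0.05. Of 12 apoptosis regulators 5 rose and Bad fell (-0.84 ± 0.15), with 5 and 2 adjusted over the list alone. The largest rise was that of the survival gene Bcl2l1 (0.99 ± 0.16).

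Large falls at 4 h were seen in genes outside the lists. Atp4b fell to dim levels by at least 1.46-fold and Srcin1 by at least 1.81-fold. Krtap12-1 (-1.99 ± 0.43), Elovl7 (-1.73 ± 0.22), the sialyltransferase gene St8sia6 (-1.65 ± 0.15), Qpct (-1.41 ± 0.34), Tsc22d1 (-1.37 ± 0.11) and Ttyh3 (-1.34 ± 0.13) fell in both genotypes. In all, 867 genes rose and 594 fell at 4 h at an adjusted p of 0.05 (limma), 269 and 38 of them by at least 2-fold. Without the intensity trend 82 rose and 4 fell. Still called there were 8 cytokine, 8 immediate early, 8 amino acid and one-carbon, 4 surface marker, 4 NF-kB, 3 interferon response and 2 ribosome biogenesis genes, 2 inhibitory receptors, 2 effector regulators, 1 negative regulator and 1 cholesterol synthesis gene, and 0 of the naive, receptor signalling, glycolysis, cytotoxic, chaperone, cell cycle, apoptosis and Nrdp1 partner lists. Leaving out the untreated Nrdp1-/- array left 221 fallen genes while leaving out its 8 h array gave 958. Centring each array on its median gave 387 fallen genes.

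**Figure D1:**
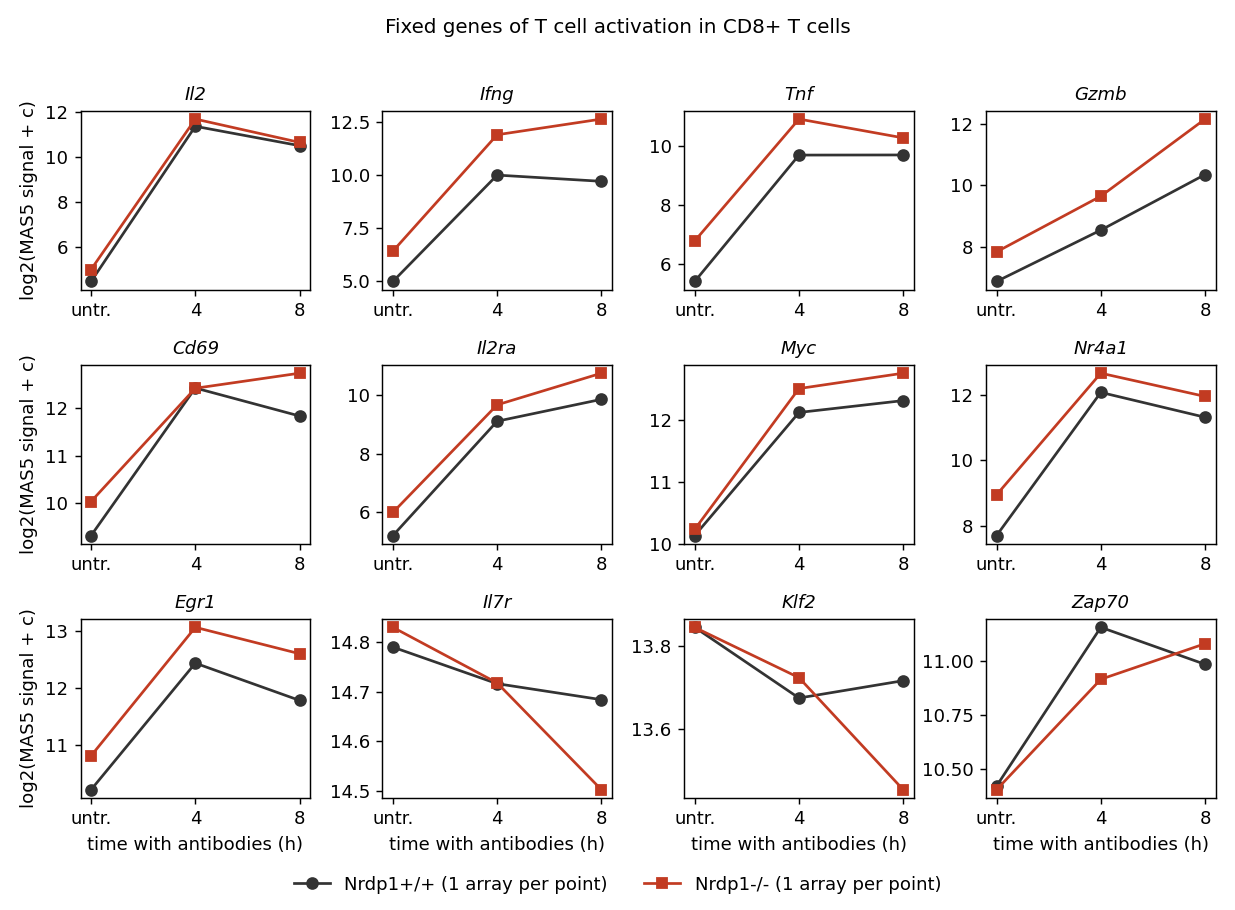
Log2(MAS5 signal + 4.45) (y axes, scaled per gene) of 12 genes fixed in advance against time with anti-CD3 and anti-CD28 (x axes, untreated, 4 h and 8 h), in wild-type (black circles) and Nrdp1-/- cells (red squares). Each point is 1 array, with no error. Ifng was higher in the Nrdp1-/- array at every time, by 1.43, 1.90 and 2.93, though it was dim in untreated wild-type cells. Il2, dim in both untreated arrays, differed by 0.32 at 4 h and 0.14 at 8 h.

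At 8 h the response was largely that of 4 h. Of the called genes 747 had risen at both times and 452 had fallen at both, with 0 genes moving in opposite directions. Both comparisons share the untreated arrays. Simulated arrays without any change gave means of 0.12 and 0.14 such genes and independent lists of these sizes 85.6 and 54.9, and neither figure covers both the effects and the shared arrays. The log2 changes at the 2 times correlated across genes with r = 0.802, against 0.50 in the simulation without change, and their covariance was 0.224 against 0.0376. Genes are not independent replicates. Il2 (5.82 ± 0.15, at least 22-fold), Ifng (5.47 ± 0.27), Csf2 (at least 6.24-fold), Cxcl9 (at least 3.52-fold), Ccl3 (5.07 ± 0.24), the branched-chain aminotransferase gene Bcat1 (at least 13.9-fold), Cth (at least 8.95-fold) and Il2ra (4.69 ± 0.17, at least 18.1-fold) led the risen genes at 8 h. Tnf had risen by 3.90 ± 0.20, Nr4a1 by 3.30 ± 0.15, Cd69 by 2.59 ± 0.18, Myc by 2.36 ± 0.11 and Egr1 by 1.68 ± 0.10. Gzmb had risen by 3.91 ± 0.19, and Zap70 by 0.62 ± 0.12. Ubash3a (-0.59 ± 0.15) and Ubash3b (-0.51 ± 0.16) had fallen. In the Nrdp1 and partner list these were the 1 risen and 2 fallen genes (1 and 3 adjusted over the list alone). Klf2 (-0.26 ± 0.10), Il7r (-0.22 ± 0.10) and Rnf41 (-0.17 ± 0.14) did not pass the threshold.

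The fixed lists held at 8 h 13 risen of 19 cytokine genes (13 adjusted over the list alone), 14 risen and 1 fallen of 24 immediate early genes (15 and 1), 11 of 13 surface markers (12), 4 of 7 inhibitory receptors (4) and 15 risen and 1 fallen of 18 NF-kB genes (15 and 1), where the number in parentheses is that adjusted over the list alone. In the same notation 25 of 28 ribosome biogenesis genes (27), 14 of 17 amino acid and one-carbon genes (14), 17 of 25 interferon response genes (18 risen and 1 fallen), 8 risen and 1 fallen of 15 glycolysis genes (8 and 1), 4 of 16 cholesterol synthesis genes (5) and 6 of 10 chaperones (6) were called. Negative regulators of signalling counted 11 risen and 3 fallen (11 and 7), effector regulators 6 and 1 (7 and 1), cytotoxic genes 3 and 1 (3 and 2), apoptosis regulators 4 and 1 (5 and 2), and G1 and S phase genes 5 and 1 (5 and 1). In the naive and quiescence list 12 fell and 1 rose (13 and 1), with Ccr9, a chemokine receptor of naive T cells, at -0.80 ± 0.10 and Pik3ip1 at -0.67 ± 0.10. Of the receptor signalling genes 8 fell and 1 rose (12 and 1), and Nfatc2, one of the fallen, again took the opposite sign (0.36) with its probe sets averaged. Of the G2 and M phase genes Mki67, Birc5 and Plk1 fell (3 adjusted over the list alone) and 0 rose, with 0 at an unadjusted p under 0.05 in that direction.

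Leading falls at 8 h included granule and macrophage genes: Prtn3 (-2.44 ± 0.39), Mpo (-2.33 ± 0.39) and Gpnmb (-2.19 ± 0.35). S100a9 fell to dim levels by at least 1.12-fold, 1110020A21Rik by at least 2.19-fold, Cenpi by at least 1.5-fold, Dusp3 by at least 1.51-fold and Ptpru by at least 1.02-fold. Of 13 measured myeloid markers 4 fell (6 adjusted over the list alone), including Csf1r (-1.34 ± 0.36). These averages cover unlike changes in the 2 genotypes. The median change of the list was -1.60 in Nrdp1-/- cells, with 2 of 13 markers positive. In wild-type cells it was -0.32, with 6 of 13 positive. S100a9 was already below the array median in untreated wild-type cells. In all, 1069 genes rose and 1001 fell at 8 h (limma), 307 and 46 by at least 2-fold. Without the intensity trend 109 rose and 6 fell. These held 9 cytokine, 9 amino acid and one-carbon, 7 immediate early, 5 surface marker, 4 ribosome biogenesis and 3 interferon response genes, 2 each of the inhibitory, effector regulator and NF-kB lists, 1 each of the negative regulator, cytotoxic, glycolysis, cholesterol and chaperone lists, and 0 of the naive, receptor signalling, cell cycle, apoptosis, Nrdp1 partner and myeloid lists. Leaving out the untreated or the 8 h Nrdp1-/- array gave 705 or 702 risen and 354 or 405 fallen genes, and leaving out the untreated wild-type or the 4 h Nrdp1-/- array gave 605 or 1512 fallen genes.

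Between 4 h and 8 h only 5 genes passed the threshold (limma), with 906 at an unadjusted p under 0.05 and 541 due by chance. Gzmb rose further by 2.16 ± 0.19 and the survival gene Bcl2 by 0.78 ± 0.10. The chemokine gene Xcl1 (-0.94 ± 0.12), the epoxide hydrolase gene Ephx1 (-1.19 ± 0.11) and Mdn1 (-0.79 ± 0.11) fell. Adjusted over the list alone, 9 immediate early, 8 NF-kB, 5 cytokine and 3 naive and quiescence genes were lower at 8 h than at 4 h, and 3 amino acid and one-carbon genes and 3 chaperones were higher. Surface markers counted 2 higher and 1 lower, cytotoxic genes 1 and 1, apoptosis regulators 1 and 2, and the inhibitory receptor, negative regulator and receptor signalling lists 1 lower gene each. This count was the least stable: 0 genes passed without the intensity trend, 7 rose and 35 fell after median centring, and leaving out any of the 6 arrays raised both counts, from 17 risen (without Nrdp1-/- at 4 h) to 48 (without untreated Nrdp1-/-) and from 13 fallen (without wild type at 4 h) to 77 (without untreated wild type).

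Nrdp1-/- cells carried more transcript of effector genes than wild-type cells over the 3 times. Ifng was higher by 2.09 ± 0.22 (limma, adjusted p = 0.000185), Tnf by 1.06 ± 0.16, Csf2 by 1.27 ± 0.28, Ccl3 by 1.17 ± 0.20, Tnfsf14 by 1.05 ± 0.24 and Ccl4 by 0.92 ± 0.10. Csf2 and Tnfsf14 were dim in both untreated arrays, and their differences at 4 h and 8 h were 0.65 and 1.25, and 0.56 and 0.74. Ifng, Tnf and Ccl3 were dim in untreated wild-type cells. Of 19 cytokine genes 9 were higher and 0 lower (12 and 1 adjusted over the list alone). Il2 (0.33 ± 0.13, adjusted p = 0.201) and Il17a (1.32 ± 0.48) did not pass the threshold. Of 11 cytotoxic genes 6 were higher (6 adjusted over the list alone): Gzmk (2.28 ± 0.10), Gzma (1.30 ± 0.14), Gzmb (1.29 ± 0.16), perforin (Prf1, 0.78 ± 0.14), Nkg7 (0.77 ± 0.16) and Ctsw (0.49). Of 12 effector regulators 4 were higher (7 adjusted over the list alone), among them Tbx21, which encodes T-bet (1.09 ± 0.17), Eomes (0.78 ± 0.11) and Bhlhe40 (1.01 ± 0.12). Of 24 immediate early genes 9 were higher and 0 lower (14 and 0 adjusted over the list alone), with Fos at 1.30 ± 0.14, Egr2 at 1.16 ± 0.12, Nr4a3 at 0.96 ± 0.13, Nr4a1 at 0.82 ± 0.12 and Egr1 at 0.68 ± 0.08. Il2ra (0.75 ± 0.14, dim in both untreated arrays) and Tnfrsf9 (0.64 ± 0.15) were the 2 called of 13 surface markers (8 adjusted over the list alone). Cd69 (0.54 ± 0.14, adjusted p = 0.0607) and Myc (0.31 ± 0.09, adjusted p = 0.0920) did not pass.

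These groups moved together with markers of other cells. Of 11 markers of memory-like CD8+ T cells 7 were higher in Nrdp1-/- cells (8 higher and 1 lower adjusted over the list alone), with Klrk1 at 1.18 ± 0.15 and Il18rap at 0.76 ± 0.10. Eomes, Ccl5 and Nkg7 stand in this list and in the effector lists. Of 13 myeloid markers 5 were higher (8 adjusted over the list alone), including the lysozyme genes Lyz1 (2.19 ± 0.32) and Lyz2 (2.18 ± 0.34). B cell markers went the other way: 10 of 12 were lower and 1, Ighm (0.51), was higher, also adjusted over the list alone. Ms4a1, which encodes CD20, differed by -3.16 ± 0.13, Blk by -2.47 ± 0.17 and the class II genes H2-Aa and H2-Eb1 by -2.45 ± 0.09 and -2.36 ± 0.11. The median of the B cell list was -1.84. Without the intensity trend 8 B cell, 1 cytotoxic (Gzmk) and 1 myeloid marker remained called, and 0 members of the cytokine, immediate early, surface marker, effector regulator and memory-like lists did.

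**Figure D2:**
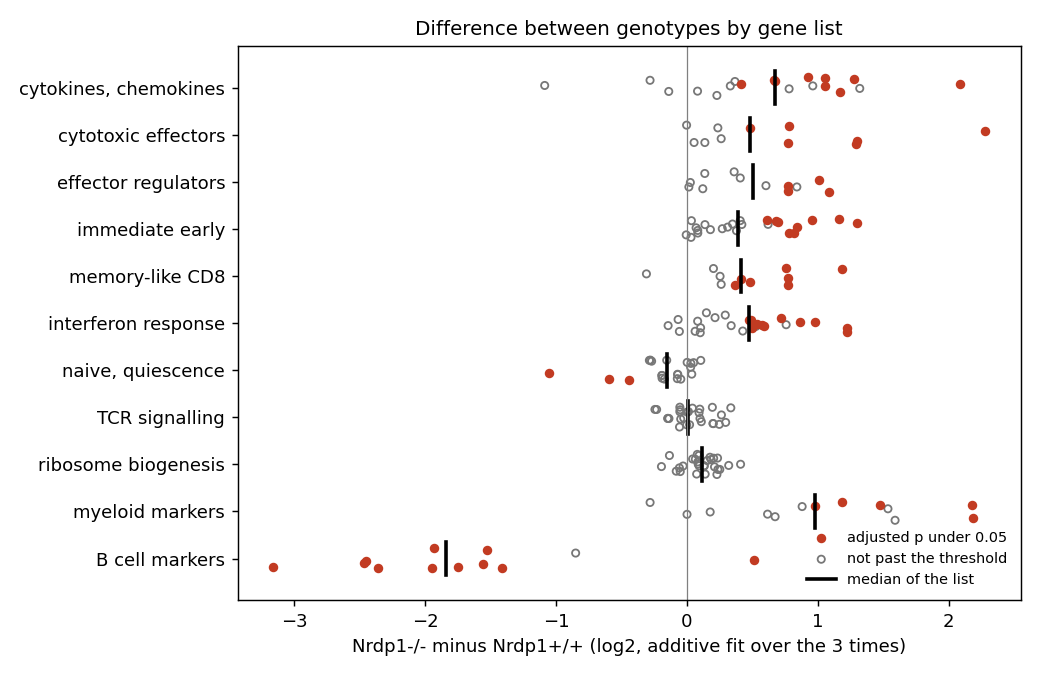
Nrdp1-/- minus wild-type difference (x axis, log2, additive limma model over the 3 times) of each measured member of 11 gene lists (rows). Filled red points passed an adjusted p of 0.05, open points did not, black bars are list medians, and vertical scatter within a row has no meaning. Medians of the effector, memory-like and myeloid lists lie above 0 and that of the B cell markers at -1.84.

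Interferon response genes were higher in Nrdp1-/- cells in 11 of 25 cases (13 adjusted over the list alone), including Mx1 (1.22 ± 0.26), Cxcl10 (1.84 at 4 h and 1.79 at 8 h, dim in untreated cells), Ifit3 (0.98 ± 0.11) and Oas1a (0.87 ± 0.12). The difference was widest at 4 h, where the median was 0.85 and 23 of 25 members were higher, against 0.19 in untreated cells and 0.34 at 8 h. Of 17 amino acid and one-carbon genes 4 were higher (7 adjusted over the list alone), led by asparagine synthetase (Asns, 1.57 ± 0.11). Among naive and quiescence genes Ccr9 (-1.05 ± 0.08), S1pr1 (-0.60 ± 0.10) and Id3 (-0.44 ± 0.10) were lower (3 of 21, and 6 adjusted over the list alone), and Klf2 (-0.07 ± 0.08) and Il7r (-0.05 ± 0.08) did not pass the threshold. Bcl2 (0.62 ± 0.08) and Fasl (0.68 ± 0.17) were higher among 12 apoptosis regulators (2 adjusted over the list alone). Of 27 components of receptor signalling and 28 ribosome biogenesis genes 0 passed in limma, also adjusted over the list alone and without the intensity trend, with 8 and 6 at an unadjusted p under 0.05. Without the intensity trend Asns and Ccr9 remained called and 0 interferon response genes did.

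The remaining lists held few calls between genotypes. Icam1 (0.37 ± 0.09) and Map3k8 (0.62 ± 0.14) were higher among 18 NF-kB genes, Socs3 (0.43 ± 0.10) among 22 negative regulators, and Cdk6 (0.48 ± 0.10) and Ccnd2 (0.40 ± 0.08) among 18 G1 and S phase genes. Mki67 was higher (0.63 ± 0.14) among 14 G2 and M phase genes. Slc16a1 was higher (0.37 ± 0.09) and Pkm lower (-0.40 ± 0.10) among 15 glycolysis genes, and Sc5d was lower (-0.44 ± 0.11) among 16 cholesterol synthesis genes. Adjusted over the list alone these counts were 2, 3 higher and 1 lower, 2, 1, 1 and 1, and 0 and 1. Among 10 chaperones and 7 inhibitory receptors 0 passed in limma and without the trend, with 4 and 2 at an unadjusted p under 0.05 and 2 and 1 adjusted over the list alone. Without the trend 0 genes of the lists of this paragraph were called.

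Some of the largest differences between genotypes were in genes dim in one of them. Gbp2b, a guanylate-binding protein gene, was dim in wild-type cells at every time and at least 59.4-fold higher in Nrdp1-/- cells. BC018473 (at least 20.2-fold), Klra16 of the Ly49 receptor family (at least 19.2-fold), Cpne4 (at least 2.71-fold), Ccnb1ip1 (at least 3.03-fold), St6galnac2 (at least 4.52-fold), Nxpe4 (at least 4.37-fold) and Arntl2 (at least 2.45-fold) were likewise higher, from dim wild-type levels. Of genes not dim throughout in either genotype, Igha, the constant region of immunoglobulin A, was higher by 3.57 ± 0.25, Emp1 by 3.20 ± 0.18, St6galnac1 by 3.17 ± 0.20 and Tnfrsf14 by 3.13 ± 0.28. Lower in Nrdp1-/- cells were Adm (-3.60 ± 0.26), the IgM receptor gene Fcmr (-3.35 ± 0.16), Sspn (-3.23 ± 0.20), Snn (-2.90 ± 0.14) and the B cell transcription factor gene Spib (-2.76 ± 0.15). Of these Tnfrsf14, Adm and Sspn were dim in 1 genotype at 2 times and St6galnac1 at 1. AF067061 (at least 2.49-fold), Nid1 (at least 2.73-fold) and Lmo7 (at least 1.98-fold) were dim in Nrdp1-/- cells. Over all genes 267 were higher and 278 lower in Nrdp1-/- cells (limma), 105 and 94 by at least 2-fold. Without the intensity trend the counts were 42 and 57. In a single simulated set with 200 changed genes 12.2% of the calls of this test were false. That share depends on the number of changed genes and is no estimate for the calls here. At all 3 times 64 genes were at least 2-fold higher and 79 at least 2-fold lower. The differences at different times, which share no array, correlated across genes with r of 0.404, 0.414 and 0.378, and by rank with 0.244, 0.337 and 0.215.

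Genotype and stimulation overlapped. Of the 267 genes higher in Nrdp1-/- cells 92 had risen with stimulation, where independent lists would share 29.3, and 35 had fallen, against 28.2. Of the 278 lower genes 91 had fallen, against 29.3, and 16 had risen, against 30.5. These counts rest on the same 6 arrays with orthogonal terms. Across disjoint arrays the genotype difference at 8 h correlated over genes with the 4 h response at r = 0.196 in wild type and 0.190 in Nrdp1-/- cells, and the difference at 4 h with the 8 h response at 0.105 and 0.0793.

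The size of the response in the 2 genotypes was compared without a test. At 8 h, 69.6% of the risen and 73.3% of the fallen genes changed more in Nrdp1-/- cells, with median differences in change of 0.13 in both sets. Median changes were 0.76 against 0.64 for risen and -0.59 against -0.45 for fallen genes. At 4 h the shares were 49.7% and 47.6%, and median centring of the arrays moved them to 61.9% and 38.0%, so no direction can be read there. Among the lists, ribosome biogenesis genes rose more in Nrdp1-/- cells at 8 h (25 of 28 members, median 0.25, 100th percentile of random lists). With median centring it was 21 of 28 members and a median of 0.19. At 4 h their median of -0.09 (2.92nd percentile) turned to 0.01 with median centring, which was applied to the lists after the data were seen. At 8 h naive and quiescence genes fell more (19 of 21 members with a negative difference, median -0.22, 0.02nd percentile). G2 and M phase genes had a median difference in change of -0.39 at 8 h (3 of 14 positive, 0.78th percentile). For negative regulators of signalling it was 0.21 at 4 h and 0.15 at 8 h (99.87th and 99.84th percentiles). With centring, the 8 h medians of the naive and quiescence list and of the G2 and M phase list were -0.29 and -0.46. Those of the negative regulators were 0.32 at 4 h and 0.09 at 8 h. The test of the genotype-by-stimulation term called 0 members of these lists. Interferon response genes rose more at 4 h in 23 of 25 cases, with a median of 0.59, and at 8 h in 14 of 25, with 0.07, and centring gave 0.69 and 0.00. Amino acid and one-carbon genes rose more in only 4 of 17 cases at 4 h, with a median of -0.29 (0.02nd percentile), or 6 and -0.19 after centring. Cytokine genes did not, with medians of -0.15 at 4 h and -0.07 at 8 h at the 8.62nd and 27.4th percentiles, though several of them, among them Il2, Csf2 and Tnfsf14, were dim in both untreated arrays. Genes that rose with stimulation were higher in untreated Nrdp1-/- cells in 65.9% (4 h) and 65% (8 h) of cases, against 47.3% of all genes.

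**Figure D3:**
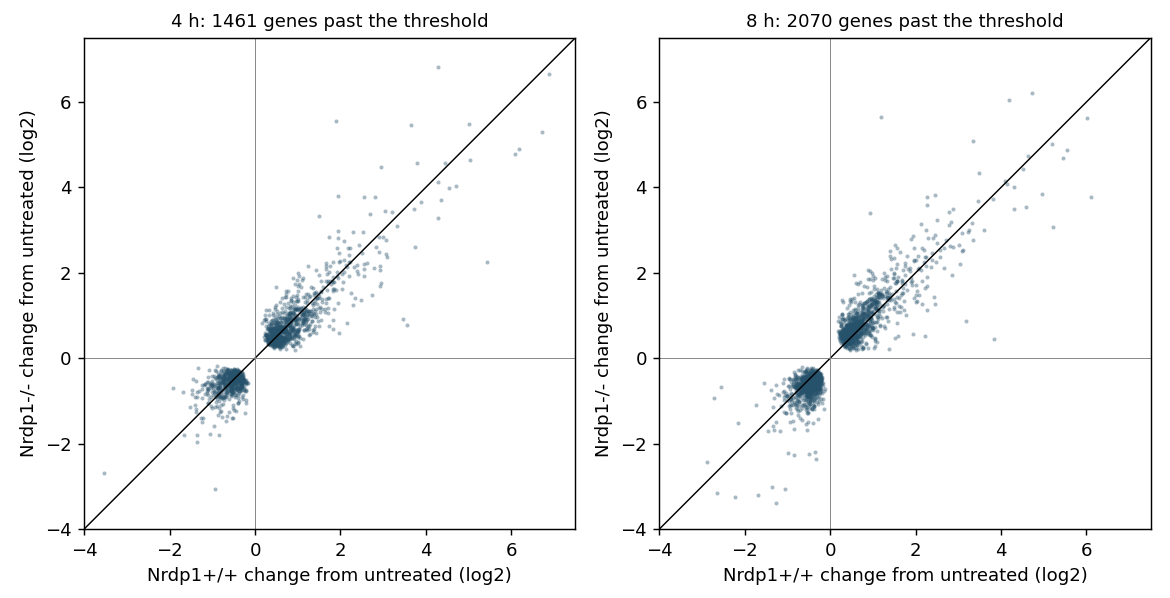
Change from untreated in Nrdp1-/- cells (y axes, log2) against that in wild-type cells (x axes, log2) for the genes called at 4 h (left, 1461 genes) and at 8 h (right, 2070 genes). Each point is a gene with 1 array per genotype and time, and the diagonal marks equal change. At 8 h 69.6% of the risen and 73.3% of the fallen genes lie on the side of the larger change in Nrdp1-/- cells.

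A test of whether the genotype difference was other in stimulated cells called 24 genes, 10 with a positive and 14 with a negative term (limma). That is few against the 401 genes at an unadjusted p under 0.05, itself below the 541 due by chance. The regulator Irf8 (1.27 ± 0.28) was induced more in Nrdp1-/- cells and Nme1 (-1.78 ± 0.23) less. Gbp2b and Cxcl10 were called with a positive term as well, but Gbp2b was dim in wild-type cells at every time and Cxcl10 in both untreated arrays, so the size of their terms rests on background. Without a test, 146 genes were induced at least 2-fold more and 139 at least 2-fold less at both times, with Rgs1 (1.20 and 1.02) and Sbf2 (1.38 and 1.39) among the former and Pmepa1 (-1.16 and -1.07) among the latter. These counts include genes that were dim in untreated cells. Both times are set against the same untreated arrays, so agreement between the times is no replication. With the spread of the additive model only 1 gene, Gbp2b, was called, and without the intensity trend 0 were.

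Differences of single arrays were of like extent at each time. In untreated cells 315 genes were at least 2-fold higher and 290 lower in the Nrdp1-/- array, at 4 h 336 and 357, and at 8 h 327 and 289. Among the most different bright genes at 4 h was Mreg (-3.30), with -0.68 in untreated cells and at 8 h. These counts fell to between 57 and 84 with a filter at the 70th percentile of the arrays.

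Markers of other tissues were few. Of 17 colon epithelium genes 3 passed the filter: Car1, Epcam and Lgals4. Epcam (log2 values of 7.47 to 9.06) and Lgals4 (8.11 to 8.81) were at or above the array median on all 6 arrays. Between genotypes Car1 was higher (2.27 ± 0.35) and Epcam lower (-1.06 ± 0.15) in Nrdp1-/- cells, also adjusted over the list alone. Car1 was dim in wild-type cells at every time, with log2 values of 5.26 to 5.35, so the size of its difference rests on background. With stimulation 0 of the colon epithelium genes changed in limma (2 lower at 8 h adjusted over the list alone). Of 5 smooth muscle genes 2 passed the filter, and 0 were called in any comparison. Cd4 was below the array median on all 6 arrays. Of the CD4+ T cell list Ikzf2 rose at 4 h (0.72 ± 0.11) and 8 h (0.47 ± 0.11), and 0 of 2 differed between genotypes (1 lower adjusted over the list alone). Of 2 natural killer and 2 erythroid genes that passed the filter 0 were called in any comparison, also adjusted over the list alone. Of the memory-like markers 1 rose and 2 fell at 4 h and 3 rose and 2 fell at 8 h (1 and 2, and 3 and 4, adjusted over the list alone). Of the B cell markers 0 were called at 4 h and Cd79b fell at 8 h (-0.65 ± 0.14, 1 adjusted over the list alone). Of the myeloid markers 0 were called at 4 h, with 1 at an unadjusted p under 0.05. Xist, the only sex-linked gene that passed the filter, was bright on all 6 arrays, with log2 values of 14.1 to 14.6, and was not called in any comparison (1 higher in Nrdp1-/- cells adjusted over the list alone).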

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

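The tests on B cell, myeloid, memory-like and immediate early genes below were chosen after the differences had been seen. The neighbour tests were set before; the wording for the splits was revised after their result, and the myeloid test was put in a second form after its first, which gave the same outcome.

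A limma test of whether the difference between Nrdp1-/- and wild-type cells changed with stimulation called 24 genes. In the simulation this test made 24 false calls, 20.5% of its calls. Here 401 genes had an unadjusted p under 0.05, below the 541 due by chance. Of the 24 called genes the rule for naming picked 16, given with the stimulated minus untreated difference on the log2 scale. It was 5.69 for Ccl1, 4.66 for Gbp2b, 3.86 for Lif, 2.16 for Sema7a, 1.77 for Cxcl10, 1.27 for Irf8, 1.09 for Slc25a40 and 1.07 for Zfas1. It was -4.20 for Rpl39, -3.07 for Lpl, -2.66 for Tnfsf11, -2.24 for Pmf1, -2.06 for 2610316D01Rik, -1.96 for Mpeg1, -1.78 for Nme1 and -1.66 for Lyz2. Mpeg1 and Lyz2 stand in the myeloid list, where 3 of 13 markers were called with a negative term (6 adjusted over the list alone). The median term of that list was -1.31, so these values may not belong to T cells. Cxcl10, Tnfsf11 and Lif were dim in both untreated arrays, Gbp2b in all wild-type arrays, and Ccl1, Sema7a, Rpl39, Lpl and Pmf1 in 1 to 3 of the 6 arrays, so the size of these 9 values rests partly on background. Only Gbp2b was still called with the spread of the additive model.

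The genotype difference itself called 545 genes. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split was the 1 that gave as many genes, and the highest of the others called 0. Only 3 of the 9 others place 1 array of each time on either side, as the model needs.

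B cell markers were lower in the Nrdp1-/- arrays. A different share of T cells with all other cells moving alike is argued against, since myeloid markers lay above B cell markers by 3.56 (bootstrap interval over genes 2.69 to 4.83) in the untreated difference. A different carry-over of B cells cannot be told apart: at the time with the fewest 91.7% of the 12 measured markers were lower, but this restates the difference that prompted the test. Untreated wild-type cells had log2 signals of 12.3 for H2-Aa, 11.5 for Ms4a1 and 14.3 for Ighm, which do not rank them across probe sets, and Ighm was higher in Nrdp1-/- cells, as was Igha outside the list, while Mzb1 was lower. Cells that secrete antibody were not tested as its source, and an effect of genotype stays open and untested.

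Effector and cytokine genes were higher in the Nrdp1-/- arrays, in 19 called members of 3 lists. The test that called these genes favours a difference that is steady over the 3 times. A small change of their difference from untreated to 8 h is thus partly selected for. RNA of myeloid cells cannot be told apart: the difference of these genes moved from untreated to 8 h by 1.15 more than that of the myeloid markers, with a bootstrap interval from -0.12 to 2.58 that includes 0, their own change being 0.11 (-0.07 to 0.27) and that of the myeloid markers -1.04 (-2.40 to 0.10). A larger share of memory-like cells cannot be told apart either: Klrc1, Klrk1 and Il18rap had an untreated median difference of 0.85 (99.96th percentile of random lists) and all 7 markers outside these lists one of 0.39, but 4 of these had already been called, and Klrd1 was lower at all 3 times. Nor can cells partly stimulated before culture, where immediate early genes had an untreated median of 0.34 (100th percentile) but had been called higher before. An effect of genotype stays open and untested, and with 1 array per group genotype and preparation share every comparison.

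Of the 143 genes that differed at least 2-fold at all 3 times, 0% lie within 50 measured genes of Rnf41, the targeted gene. That window held only 74 genes, of which 5 were called between genotypes against 3.72 expected. A fit had been set at 50% or more of the 143 genes, which 74 genes could hardly supply. The test therefore cannot decide on DNA carried along around the targeted gene, and a longer stretch was not tested. Segments of another strain's DNA elsewhere are a candidate explanation: 42 of the 143 genes had another of them within 5 measured genes, against a median of 18 in matched random sets, at the 100th percentile of 1000 sets. Without the members of the B cell and myeloid lists and genes named as immunoglobulin or H2 genes, a check added later, it was 35 of 126 against a median of 14. B cell genes outside those lists stayed in, among them Spib, Blnk and Syk, each with such a neighbour. The check therefore does not remove cell type as a source of the grouping. Rnf157, St6galnac2, BC018473 and St6galnac1 form 1 such group, all higher, and Gm20767, AF067061, BC147527 and Tcstv3 another, all lower. The labels name C57/BL6 for both genotypes, and genes of 1 cell type can also lie together, so the genotype itself stays open and untested.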

How the results depend on the processing

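The interaction test with the additive spread, and centring for the list medians of the difference in change, were added after the data were seen. Causes of the shifts below were not tested. Without the intensity trend, genes risen and fallen were 82 and 4 at 4 h, 109 and 6 at 8 h and 0 and 0 between the times, 42 and 57 genes differed by genotype, 0 and 0 by the interaction, and the shares with the larger change in Nrdp1-/- cells at 8 h were 61.5% and 66.7%. Of 270 called values of named genes 89 stayed called there. A 2-fold minimum, which can only remove genes, left 269 and 38, 307 and 46, 1 and 1, and 105 and 94. Median centring gave 387 fallen at 4 h, 7 risen and 35 fallen between the times, 5 and 8 interaction genes, and shares of 61.9%, 38.0%, 63.6% and 82.2% (risen and fallen at 4 h, then at 8 h). Quantile normalization gave 3 and 2 interaction genes, and the additive spread 1 and 0. Averaging probe sets gave 2 and 0 interaction genes, 1 risen between the times, a share of 69.8% of genes fallen at 8 h, and turned Nfatc2 to 0.23 at 4 h and 0.36 at 8 h, neither called. The pseudocount at the 30th percentile gave 8 fallen between the times. Genes at least 2-fold apart (higher and lower; untreated, 4 h, 8 h) were 1597 and 1744, 1639 and 2152, and 1918 and 1482 without a filter, since dim genes then count, and 84 and 57, 80 and 72, and 69 and 76 with the stricter one, since fewer genes are tested. Leaving out each array in turn, where the lone array of a time is assumed to vary like the others, gave 221 (without untreated Nrdp1-/-) to 958 (without its 8 h array) fallen at 4 h, 702 to 1301 risen and 354 to 1512 fallen at 8 h, and 17 to 48 risen and 13 to 77 fallen between the times. The genotype counts stayed within 1.5 times, at 267 to 304 higher and 241 to 309 lower, and the interaction could not be fitted without an array. In the stimulated arrays alone 286 genes were higher and 278 lower. Except for Nfatc2 no called value of a named gene changed sign under these settings. The labels carry no replicate numbers. With time as a term, each Nrdp1-/- array is set against the wild-type array of its time, and the labels name no other pairing. Signal over background limits dim genes, for which bounds are given.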

Other observations

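Genes of immunoglobulins and B cells did not all differ in 1 direction. Jchain, the joining chain of polymeric immunoglobulins, was higher in the Nrdp1-/- arrays by 1.83, 1.47 and 1.72 in untreated cells, at 4 h and at 8 h, and Igha by 4.55, 3.48 and 2.67. Of the genes at least 2-fold apart at all 3 times, 3 kappa variable segments were higher too, among them Igkv6-14 (2.60, 1.70 and 1.44). Mzb1, a gene of B cells and antibody-secreting cells (-1.57, -1.71 and -2.36), and the variable segment Ighv14-2 (-2.37, -1.74 and -1.89) were lower. The B cell signalling genes Blnk (-1.46, -2.28 and -2.62), Btk (-1.16, -1.11 and -1.47) and Syk (-1.63, -1.77 and -2.31) were lower. Mcpt8 (1.63, 2.06 and 1.68) and Ms4a2 (1.47, 1.44 and 1.38), 2 genes known from basophils and mast cells, were higher, and no list of such genes was tested. Klrg1, a receptor of differentiated effector T cells, was higher by 1.40, 2.64 and 1.64. These genes were picked after their values were seen, and each difference is between 1 array and 1 array.

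The median difference of the myeloid markers between Nrdp1-/- and wild-type cells was 1.65 in untreated cells, 0.98 at 4 h and 0.72 at 8 h. From untreated to 8 h the difference changed by a median of -1.04, with a bootstrap interval over genes of -2.40 to 0.10 that includes 0. In 5 of 13 markers it moved up. Each difference is between 1 array and 1 array, so a decrease is not established. The B cell median was nearly constant, at -1.91, -1.76 and -1.79.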
